A study of Homo sapiens with 6 samples.

How the data were processed

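Total RNA from Jurkat cells, a human leukaemic T-cell line, was sequenced in 6 libraries. Per the labels' protocols, RNA was isolated with a column kit and made into libraries with an Agilent SureSelect XT HS2 kit without poly-A selection, in a procedure described for circular RNA or RNA immunoprecipitation samples. Structured noncoding RNA therefore stays in the libraries. Per the submitters' processing notes, the tools were bcl2fastq, Trimmomatic 0.36, StringTie and edgeR, and the genome build was GRCh38.p6. The aligner, the circRNA caller and any use of molecular barcodes are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The 3 libraries titled with phorbol myristate acetate (PMA, 20 ng/mL) and ionomycin (500 ng/mL) for 24 h are called PMA-labelled, and the 3 titled with culture medium for 24 h are called medium-labelled. The word labelled is kept because genes known to be induced by this treatment lay lower in the PMA-labelled libraries. The submitters' other names for the same libraries sound opposite to the titles. Short sample names begin with Neg for the PMA-labelled libraries and with pos for the medium-labelled ones, and the authors' sheet codes the groups as C and T in that order. No source used here says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

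Gene values are the authors' deposited TPM (transcripts per 1000000 transcripts) for 60671 genes. In the values themselves, each library has the fixed sum of TPM values once the genes listed at exactly 0.0001 are set aside, so 0.0001 was taken as the authors' floor for genes with no signal. TPM keeps no depth, so no count test was run on genes and no counting interval can be given for them. Of the gene IDs, 58453 (96.3%) were found in GENCODE 29, which supplied gene types. Gene positions are those in the authors' deposited gene table. Because TPM is a share of a total, a large change in abundant noncoding RNA would move every other gene. The authors' deposited circRNA tables hold the count of back-splice junction reads (reads across the junction that closes a circle) for 22536 circRNAs, with no normalization. They also hold the junction ratio, a fraction between 0 and 1 made by the authors for each junction, whose formula and linear read counts are not given in the sources used here. The authors' deposited table of their own comparison gives a log2 fold change, a log2 CPM (back-splice count scaled to library size), a likelihood ratio score, a p-value and a false discovery rate for each circRNA. The sign of that log2 fold change in the authors' deposited table was opposite to PMA-labelled minus medium-labelled in 97.7% of circRNAs. The authors' deposited sheet of read totals gives total and mapped reads, and its count of circular reads was 2 times the sum of back-splice reads in each library.

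Depth differed between libraries. Total reads were 44119608, 108599074 and 79368772 in PMA-labelled libraries 1 to 3, and 58078904, 49521152 and 60300872 in medium-labelled libraries 1 to 3, of which 92.4% to 93.2% mapped. Back-splice reads came to 6789, 17872 and 13824 in the PMA-labelled libraries and 10745, 8180 and 13696 in the medium-labelled ones. Of the circRNAs, 12883 (57.2%) had 1 read over all libraries. A chi-square comparison of back-splice counts between each pair of libraries gave 1.57 to 2.11 times its degrees of freedom, so no library was counted as a repeat of another. Read intervals and limits of a count of 0 (3 reads) cover counting error only. A fold against a group with no read is the smaller of those scaled to back-splice reads and to mapped reads, against 3 reads over the group. It takes the reads of the other group as exact, so it is not a lower confidence bound.

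Gene expression was compared with limma 3.58.1 (R 4.3.3) on log2(TPM + 1), for the 4816 genes with a TPM of at least 1 in at least 3 libraries. All log2 fold changes are PMA-labelled minus medium-labelled on this scale, which understates the change of low genes. Back-splice counts were compared with the edgeR 4.0.16 quasi-likelihood test, with TMM factors over back-splice reads, for the 1278 circRNAs with at least 2 reads in at least 3 libraries. Junction ratios were compared with limma on the arcsine of the square root, for the 1273 of these circRNAs that varied, with a ratio of 0 kept where a library had no back-splice read. Library-level measures were compared with a two-sided exact permutation test of the difference of means, whose smallest possible p with 3 libraries against 3 is 0.1. The change of each circRNA was set against that of its host gene by Spearman correlation. Benjamini-Hochberg adjusted p of 0.05 was the threshold throughout.

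Before the data were examined, 29 gene lists were fixed for T-cell activation, calcium and NF-kB signalling, T-cell receptor signalling, the thymocyte programme, cytokines, metabolism, the cell cycle, apoptosis, interferon response, circRNA formation, stress, ribosomes, histones, noncoding RNA and markers of other cell types. They name 715 genes, of which 689 were in the gene table. The 21 lists with at least 5 tested members were compared with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it. A rule was fixed at the same time for the genes to name. It took the largest changes past the threshold with a mean TPM of at least 5 in the higher group. For each list it took the up to 4 largest changes past the threshold or, with none, the 2 most abundant members. It always took PC, CAMTA1, IL2 and CD69. For circRNAs and junction ratios it took the 5 smallest p in each direction when fewer than 3 passed, with the 5 circRNAs of most reads. It also took the CAMTA1 circRNAs that pass the count minimum, of which there were none. Some genes, one taken by this rule among them, are not reported here. Exon numbers are those of a GENCODE 29 basic transcript whose exon ends match both ends of the circRNA.

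The tests were tested on simulated data made from the real libraries. For genes, changes were set on the log2(TPM + 1) scale, where a step is a larger fold of TPM itself in low genes. On this scale 31 of 67 simulated 2-fold changes were recovered, 64 of 67 4-fold changes and 66 of 66 8-fold changes. These counts overstate the recovery of equal folds of TPM in low genes. Of 4616 unchanged genes 8 were called. For lists in which every member was moved 2-fold on the same scale, 21 of 21 were recovered. Genes were simulated as independent of each other. The estimated correlation between members was 0.331 to 0.670 in the 5 real lists past the threshold. This recovery thus holds for uncorrelated members only, and false list calls were not counted. For circRNA counts, 0 of 67 simulated 2-fold changes, 14 of 67 4-fold changes and 29 of 66 8-fold changes were recovered, with 1 of 1078 unchanged circRNAs called. Among circRNAs with at least 50 reads in all, 6 of 9 4-fold changes were recovered and 8 of 8 8-fold changes. For junction ratios, shifts of 0.2, 0.4 and 0.6 on the arcsine scale were recovered in 0 of 40 circRNAs each, a shift of 0.8 in 3 of 40 and a shift of 1.2 in 12 of 40.

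Other settings, fixed at the same time as the lists, were pseudocounts of 0.1 and 5, no minimum and a minimum of 5 for TPM and reads, quantile and median-ratio scaling, a trended variance, DESeq2 1.42.0, library sizes from mapped reads, the untransformed ratio, circRNAs read in every library, thinning to the smallest library, leaving out each library, and the replicate number as a block. Added after seeing the data were leaving out medium-labelled libraries 2 and 3 together (for lists also with an estimated correlation) and rescaling TPM to protein-coding genes. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. No named circRNA of the study's title was matched, since the sources used here give no identifier or position for it.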

Results

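Circular RNAs (circRNAs), closed RNA molecules made when a downstream splice site joins an upstream one, were measured with gene expression in Jurkat T cells. The study asked how circRNA levels respond to stimulation with PMA, an activator of protein kinase C, and ionomycin, a calcium ionophore, which together mimic signalling from the T-cell receptor. There were 3 PMA-labelled and 3 medium-labelled libraries, all taken at 24 h. Most of the RNA measured was structured noncoding RNA. RNA of the misc_RNA class took a mean of 48.2% of TPM over the 6 libraries, small nuclear RNA 28.9%, ribozyme RNA 11.8% and protein-coding genes 6.30%. The signal recognition particle RNA RN7SL2 alone stood at 179005 ± 5830 TPM in the PMA-labelled and 191796 ± 18180 TPM in the medium-labelled libraries (SD, n = 3 each). Protein-coding genes took 6.60% ± 0.242 of TPM in the PMA-labelled libraries (SD, n = 3) and 6.84%, 6.63% and 4.52% in medium-labelled libraries 1 to 3.

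The immediate early genes FOSB, IER3 and NR4A1 were lower in the PMA-labelled than in the medium-labelled libraries. FOSB, a subunit of the AP-1 transcription factor, was at 0.625 ± 0.183 TPM in the PMA-labelled and 16.5 ± 5.21 TPM in the medium-labelled libraries (SD, n = 3 each), a ratio of 26.3. IER3, a short-lived stress-response gene, was at 0.395 ± 0.120 against 4.93 ± 0.912 TPM, and NR4A1, an orphan nuclear receptor induced by T-cell receptor signals, at 1.22 ± 0.558 against 9.46 ± 3.07 TPM. These genes are known to be induced transiently by PMA and ionomycin. The libraries were taken at 24 h only, so whether an ended response bears on these values was not tested. IL2, the cytokine by which Jurkat activation is usually read, was at the floor in all 6 libraries.

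Of 4816 genes tested with limma, 3 passed the threshold, with 0 higher and 3 lower in the PMA-labelled libraries. FOSB (ENSG00000125740, chromosome 19, 45467995 to 45475179) had a log2 fold change of -3.38 (SE 0.28, adjusted p = 0.0005). IER3 (ENSG00000137331, chromosome 6, 30743199 to 30744548) had -2.08 (SE 0.23, adjusted p = 0.00516), and NR4A1 (ENSG00000123358, chromosome 12, 52022832 to 52059507) had -2.22 (SE 0.29, adjusted p = 0.0173). In each of the 3 genes, all 3 PMA-labelled libraries lay below all 3 medium-labelled ones. At an unadjusted threshold of 0.05 there were 211 genes, 113 lower and 98 higher. Groups did not overlap in 399 genes (8.28%), where chance gives 10%. The count was 10 under median-ratio scaling (2 higher, 8 lower) and 8 with TPM rescaled to protein-coding genes (1 higher, 7 lower). That rescaling kept the pseudocount of 1 on larger values, so it also acted as a smaller pseudocount. The count was 0 at a pseudocount of 5 and 0 without the TPM minimum. Without the TPM minimum the log2 fold changes of the 3 genes were unchanged. The count was 19 without medium-labelled library 1 and 5 without medium-labelled library 2. NR4A1 lost its call without PMA-labelled library 2 (log2 fold change -2.07, adjusted p = 0.0948) or 3 (log2 fold change -2.18, adjusted p = 0.0696).

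**Figure D1:**
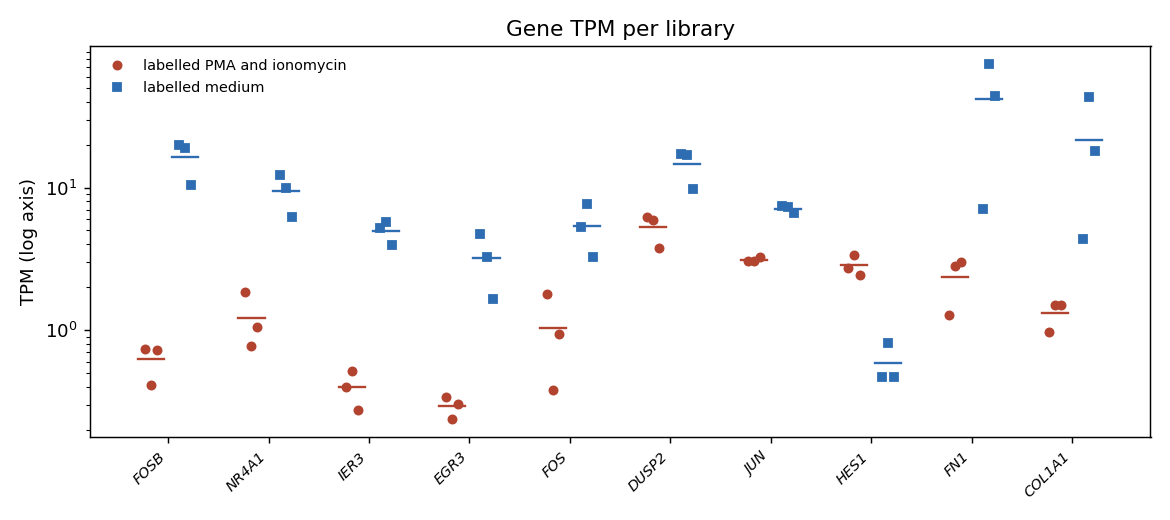
TPM on a log axis of 10 genes in each library, with 3 PMA-labelled libraries as red circles, 3 medium-labelled libraries as blue squares and a bar at each group mean. FOSB, NR4A1 and IER3 passed the test over all genes, with FOSB at 0.413 to 0.739 TPM in the PMA-labelled and 10.5 to 19.9 TPM in the medium-labelled libraries; the others did not pass and were chosen after their values were seen, apart from COL1A1.

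Most tested genes of the activation lists lay lower in the PMA-labelled libraries, though both list calls rested on the preset correlation. In the list of immediate early genes and AP-1 subunits, 13 of 16 tested members had negative log2 fold changes, 2 (FOSB and IER3) passed over all genes and 8 passed when adjusted over the list alone. Its median log2 fold change was -0.71 (camera adjusted p = 1.65e-18, and adjusted p = 0.413 with an estimated correlation). The list of activation-induced T-cell genes overlaps with that list, which holds all of its tested members but NR4A1, NFATC1 and DUSP2. The 2 lists are thus not separate evidence. Of the activation-induced genes, 6 of 6 tested members were negative, 1 (NR4A1) passed over all genes and 4 passed when adjusted over the list alone, all lower. The median was -1.16 (camera adjusted p = 3.17e-15, and adjusted p = 0.276 with an estimated correlation). Under other pseudocounts, scalings and no TPM minimum the medians ran from -1.15 to -0.38 and from -2.14 to -0.36. Members chosen here after their values were seen include EGR3, a zinc-finger transcription factor, at 0.292 ± 0.0517 against 3.21 ± 1.53 TPM, DUSP2, a phosphatase of MAP kinases, at 5.29 ± 1.35 against 14.6 ± 4.21 TPM, and JUN at 3.10 ± 0.109 against 7.08 ± 0.384 TPM (PMA-labelled against medium-labelled, SD, n = 3 each). EGR3, DUSP2 and JUN passed over their lists alone and not over all genes. Over all genes EGR3 passed at a pseudocount of 0.1 (adjusted p = 0.0443), under median-ratio scaling (0.0372), with TPM rescaled to protein-coding genes (0.00359) and without medium-labelled library 3 (0.0252), and DUSP2 under median-ratio scaling (0.0372). MYC, of the AP-1 and immediate early list and also chosen after its values were seen, was at 16.7 ± 8.66 against 12.5 ± 4.04 TPM and did not pass. CD69, an early surface marker of T-cell activation, was at 0.401 ± 0.161 against 1.22 ± 0.420 TPM, without overlap, but was too low to be tested. Another 12 of the 36 activation-induced genes, IL2 among them, were at the floor in all 6 libraries.

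Collagen and other matrix genes differed within the medium-labelled group, beside these activation genes. COL1A1, a chain of type I collagen, was at 4.36, 42.8 and 17.9 TPM in medium-labelled libraries 1 to 3, and at 0.973 to 1.51 TPM in the PMA-labelled libraries. Its log2 fold change of -2.83 (SE 0.58, limma adjusted p = 0.229) did not pass over all genes. In the list of fibroblast and epithelial markers, 3 genes were tested (COL1A1, COL1A2 and COL3A1), and all 3 passed when adjusted over the list alone, lower in the PMA-labelled libraries. All 3 passed over all genes without medium-labelled library 1, with an adjusted p of 0.00254 for COL1A1. Without the TPM minimum all 12 members were tested and the list passed, with 8 negative members and a median of -0.39 (camera adjusted p = 0.00418, and adjusted p = 0.794 with an estimated correlation). With medium-labelled libraries 2 and 3 both left out, an alternative added after seeing the data that assumes the remaining library to vary like the others, 3 genes passed (1 higher, 2 lower). FOSB was among them, while IER3 had a log2 fold change of -2.15 (adjusted p = 0.0653) and NR4A1 of -2.61 (adjusted p = 0.0966), against -2.08 and -2.22 with all libraries. The median log2 fold change was then -0.96 for the AP-1 and immediate early list (camera adjusted p = 6.52e-13 at the preset correlation) and -1.32 for the activation-induced list (adjusted p = 4.09e-11). Both calls were lost with an estimated correlation (adjusted p = 0.613 each).

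NF-kB targets, mitochondrially encoded genes and histones also passed the list test. Among NF-kB targets, 4 of 6 tested members were negative and 1 passed, IER3, which is also in the immediate early list. The median was -0.09 (camera adjusted p = 0.00677, and adjusted p = 0.496 with an estimated correlation), and the call was lost without medium-labelled library 3 (median -0.19, adjusted p = 0.0719) and without the TPM minimum (median -0.03, adjusted p = 0.300). The median was -0.24 without PMA-labelled library 1, -0.01 without PMA-labelled library 3 and -0.06 without medium-labelled library 1. Of the 15 mitochondrially encoded genes, 13 were negative and 0 passed singly or when adjusted over the list alone, with a median of -0.65 (camera adjusted p = 9.83e-10, and adjusted p = 0.496 with an estimated correlation) and of -0.31 without medium-labelled library 2. The respiratory chain subunit MT-CO1 (chosen after its values were seen) was at 78.5 ± 8.22 against 107 ± 40.9 TPM, while the ribosomal RNA MT-RNR1 was at 896 ± 268 against 947 ± 622 TPM (SD, n = 3 each) with a log2 fold change of 0.14. Of 36 names in the list of replication-dependent histone genes, which package newly made DNA, 18 were in the gene table. All 16 tested members had positive log2 fold changes and 0 passed singly or when adjusted over the list alone. Their median was 0.47 (camera adjusted p = 2.81e-06, and adjusted p = 0.586 with an estimated correlation), and it was 0.17 under quantile normalization and 0.17 without medium-labelled library 3. The most abundant of these 16, H4C4, was at 2481 ± 84.0 against 2162 ± 88.5 TPM. Without medium-labelled libraries 2 and 3, the highest in COL1A1, the adjusted p was 0.0749 for NF-kB targets (median -0.15), 0.0701 for mitochondrially encoded genes (median -0.23) and 0.248 for histones (median 0.04). A set of 64 histone genes in the gene table took 61.1% of protein-coding TPM in medium-labelled library 2 and 66.2% in library 3. Their share was 68.0% to 70.9% in the other 4 libraries. By fry, 0 of the 21 lists passed for movement in 1 direction, with an adjusted p of 0.0986 for the activation-induced list. For change in either direction, fry gave adjusted p of 0.0166 for the activation-induced list, 0.00322 for AP-1 and immediate early genes, 0.00111 for NF-kB targets and 0.000207 for the thymocyte programme.

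The lists of T-cell identity and growth did not pass camera's test. T-cell receptor genes had a median log2 fold change of 0.08 over 18 tested members (camera adjusted p = 0.954). The kinase LCK was at 24.2 ± 2.81 against 23.6 ± 6.93 TPM, and CD3E, a chain of the receptor complex, at 13.4 ± 0.875 against 14.4 ± 7.57 TPM (SD, n = 3 each). NFAT and calcium signalling genes had a median of 0.05 and a mean of 0.02 over 15 members, while camera, which compares them with all other genes, pointed down (adjusted p = 0.954). Calmodulin gene CALM3 was at 19.2 ± 0.944 against 19.8 ± 5.44 TPM and the calcium pump ATP2A3 at 12.4 ± 2.14 against 9.93 ± 1.74 TPM. The thymocyte and leukaemia programme had a median of 0.03 over 11 members (adjusted p = 0.217), although it passed fry's test for change in either direction (adjusted p = 0.000207), and HES1, a Notch target, passed over the list alone (and was chosen for that) at 2.85 ± 0.481 against 0.583 ± 0.196 TPM (log2 fold change 1.28, limma adjusted p = 0.111 over all genes, 0.0372 under median-ratio scaling and 0.0388 with TPM rescaled to protein-coding genes). S-phase genes had a median of 0.10 over 23 members (adjusted p = 0.424) and G2/M genes 0.03 over 18 (adjusted p = 0.981), with the replication helicase subunit MCM7 at 13.2 ± 0.785 against 14.0 ± 3.36 TPM. Apoptosis genes had a median of 0.07 and a mean of -0.00 over 7 (adjusted p = 0.954). Ribosomal protein genes had a median of 0.02 and a mean of -0.05 over 45 (adjusted p = 0.313). Heat shock and stress genes had -0.02 over 17 (adjusted p = 0.183, and 0.0481 without medium-labelled library 1), with 1 lower member past over the list alone, HSP90B1, an endoplasmic reticulum chaperone chosen after its values were seen.

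Metabolic lists did not pass camera's test in the comparison as set beforehand, though 2 of them passed under other settings. PC, the pyruvate carboxylase named in the study's title, was at 1.31 ± 0.580 TPM in the PMA-labelled and 1.12 ± 0.384 TPM in the medium-labelled libraries (SD, n = 3 each), a log2 fold change of 0.11 (SE 0.27, limma adjusted p = 0.999). Pyruvate and citrate cycle genes had a median of -0.09 over 23 members (camera adjusted p = 0.183), glycolysis genes -0.05 over 19 (adjusted p = 0.0570), nuclear genes of oxidative phosphorylation -0.07 over 24 (adjusted p = 0.0635) and cholesterol synthesis genes -0.00 over 19 (adjusted p = 0.336). GAPDH was at 153 ± 1.32 against 163 ± 43.9 TPM, and IDH2, a mitochondrial isocitrate dehydrogenase, at 14.3 ± 1.35 against 13.1 ± 3.76 TPM. Glycolysis passed, lower in the PMA-labelled libraries, under quantile normalization (adjusted p = 0.00947), median-ratio scaling (adjusted p = 0.0191), a pseudocount of 5 (adjusted p = 0.0301), TPM rescaled to protein-coding genes (adjusted p = 0.0225), the replicate block (adjusted p = 0.0489) and without medium-labelled library 3 (adjusted p = 0.00674) or PMA-labelled library 2 (adjusted p = 0.0356). Nuclear genes of oxidative phosphorylation passed, also lower, without PMA-labelled library 2 (adjusted p = 0.0356), without medium-labelled library 1 (adjusted p = 0.0481) and with the replicate block (adjusted p = 0.0489). With an estimated correlation the adjusted p was 0.921 for both lists, and without medium-labelled library 2 both medians were 0.09.

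Other lists of at least 5 tested members did not pass camera's test in the comparison as set beforehand. Interferon-stimulated genes had a median of 0.24 over 7 members (adjusted p = 0.217), of which IRF1 and IFITM1, chosen after their values were seen, passed over the list alone, both higher. Genes of circRNA formation and turnover had a median of 0.04 over 22 (adjusted p = 0.954). Structured noncoding RNA had 0.23 over 19 (adjusted p = 0.0635, and adjusted p = 0.496 with an estimated correlation). At the preset correlation it passed, higher in the PMA-labelled libraries, at a pseudocount of 5 (adjusted p = 0.0211), a TPM minimum of 5 (0.0442), with the replicate block (0.0489), without PMA-labelled library 2 (0.0356), medium-labelled library 2 (0.0227) or medium-labelled library 3 (0.00674), and with both of the latter left out (0.00312). Nuclear long noncoding RNA had 0.17 over 7 (adjusted p = 0.583), with GAS5 at 9.46 ± 1.47 against 6.12 ± 0.583 TPM (SD, n = 3 each). Lists with fewer than 5 tested members had no list test in this comparison. Without the TPM minimum all 8 were tested, and the fibroblast and epithelial list was the one that passed. Log2 fold changes were 0.31 for LAIR1 of the inhibitory receptors, -0.05 for TGFB1 and 0.37 for IL32 of the cytokines, -0.10 for CDKN2C and 0.39 for CDKN2D of the cell-cycle inhibitors, 0.02 for IGKC of B cells, 0.60 for LYZ and -0.46 for VCAN of monocytes, and 0.24 for GZMA of cytotoxic cells, with 0 past. The globin genes HBB and HBA2 of the erythroid list had 1.01 and 1.17 and did not pass, with HBB at 8.12 TPM in PMA-labelled library 1.

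No circRNA differed between the groups past the threshold. The most abundant circRNA, exon 2 of GSE1 (chromosome 16, 85633914 to 85634132), had 214, 533 and 348 reads in PMA-labelled libraries 1 to 3 and 293, 246 and 385 reads in medium-labelled libraries 1 to 3. That is 5.07 ± 0.312 against 5.90 ± 0.860 RPM (reads per 1000000 mapped reads, SD, n = 3 each). Exons 2 and 3 of ZKSCAN1 (chromosome 7, 100023419 to 100024307) stood at 0.580 ± 0.0370 against 1.05 ± 0.228 RPM, with a log2 fold change of -0.59 that did not pass. Of the other 3 most abundant, exons 3 and 4 of VAMP3 (chromosome 1, 7777160 to 7778169) had 121 reads over the PMA-labelled and 99 over the medium-labelled libraries, and exons 29 to 31 of GCN1 (chromosome 12, 120154970 to 120155719) 104 and 100. Exons 2 to 4 of ASXL1 (chromosome 20, 32366384 to 32369123) ranged from 5 to 79 reads within the PMA-labelled group.

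Of 1278 circRNAs tested with edgeR, 0 passed, and the smallest adjusted p was 0.991. At an unadjusted threshold of 0.05 there were 42 (18 higher, 24 lower) by edgeR and 13 by DESeq2, which also called 0. The authors' deposited table marks 0 circRNAs as changed, with 124 at p under 0.05 and a smallest false discovery rate of 0.109. The tested circRNAs held 43.6% of back-splice reads, with a median of 15 reads over the 6 libraries, and 0 of 67 simulated 2-fold changes were recovered at this depth. Without the read minimum, 1 of 22536 passed, higher in the PMA-labelled libraries (chromosome 6, 57919784 to 57930291, exons 1 to 5 of GUSBP4, a pseudogene whose reads can be shared with related copies). It was chosen after its values were seen and had 0, 14 and 26 reads against 0, 0 and 0 and an edgeR adjusted p of 0.000227. Against a floor of 3 reads over the group, and with its own reads taken as exact, it was 9.62-fold higher. It had no read in PMA-labelled library 1.

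The 5 circRNAs with the smallest p in each direction did not pass. Higher in the PMA-labelled libraries were exons 2 and 3 of PPP6R2 (chromosome 22, 50372020 to 50394135) with 30 reads against 5, exons 2 and 3 of SLC4A4 (chromosome 4, 71236576 to 71255399) with 16 against 1, and exons 6 and 7 of BROX (chromosome 1, 222724092 to 222725555) with 15 against 1. An exonic circRNA of CDC42 (chromosome 1, 22078429 to 22091501) had 9 against 0, and exons 3 and 4 of XPO1 (chromosome 2, 61522611 to 61526521) had 46 against 15. Lower were an intergenic circRNA (chromosome X, 65075474 to 65113813) with 1 read against 16, exons 2 to 4 of FAM193B (chromosome 5, 177536358 to 177539147) with 4 against 22, and exons 2 to 6 of TIMM23 (chromosome 10, 45975454 to 45988847) with 0 against 10. Exons 2 to 7 of PPA2 (chromosome 4, 105424196 to 105456745) also had 0 against 10, and exons 7 and 8 of ERCC4 (chromosome 16, 13934192 to 13935743) had 0 against 9. The next folds are against a floor of 3 reads over the group, with the observed reads taken as exact. TIMM23 and PPA2 were each 3.93-fold and ERCC4 3.54-fold higher in the medium-labelled libraries, and CDC42 2.16-fold higher in the PMA-labelled ones. In all, 60 circRNAs had reads in all 3 PMA-labelled libraries and none of the others, and 61 had reads in all 3 medium-labelled libraries and none of the others.

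**Figure D2:**
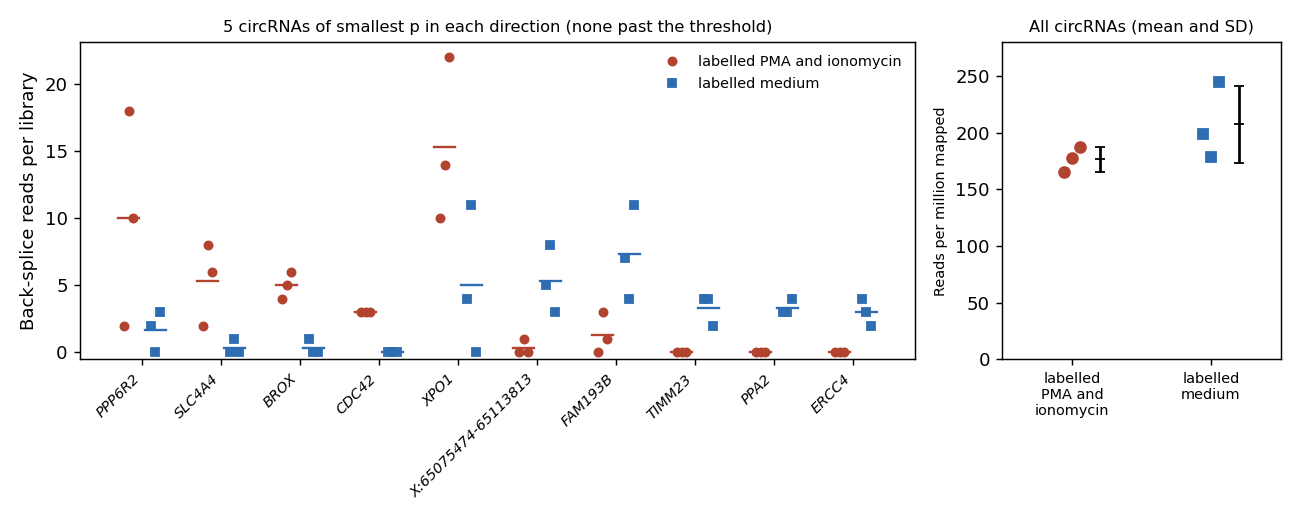
Left, back-splice reads per library of the 5 circRNAs with the smallest p in each direction, named by host gene or position, with 3 PMA-labelled libraries as red circles, 3 medium-labelled libraries as blue squares and a bar at each group mean; none passed the threshold. Right, back-splice reads per 1000000 mapped reads in each library, with the mean and SD of each group in black (177 ± 11.1 and 208 ± 34.0).

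CAMTA1, a calmodulin-binding transcription activator whose symbol the study's title carries, gave few reads. The gene was listed at the floor in all 3 PMA-labelled libraries, and at 0.414, 0.0001 and 0.0216 TPM in medium-labelled libraries 1 to 3, and was too low to be tested. Of 4 circRNAs annotated to it, 0 passed the read minimum. Exons 2 and 3 (of 4) of a CAMTA1 transcript (chromosome 1, 6806983 to 6825210) had 0 reads in each PMA-labelled library and 5, 2 and 1 reads in medium-labelled libraries 1 to 3. Against a floor of 3 reads over the group it was 3.15-fold higher in the medium-labelled libraries. That fold takes its 8 reads as exact, and 5 of them came from medium-labelled library 1. Its 5 reads in medium-labelled library 1 were 465 per 1000000 back-splice reads (95% exact Clopper-Pearson interval 151 to 1090), and the 0 reads in PMA-labelled libraries 1 to 3 allow up to 442, 168 and 217 per 1000000. Without the read minimum its edgeR adjusted p was 0.446, and its false discovery rate in the authors' deposited table was 0.518. The other 3, all intronic, had 1 read each. None was matched to the circRNA of the study's title, for which no position is given in the sources used here.

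Junction ratios, fractions made by the authors for each back-splice junction by a formula not given in the sources used here, did not differ past the threshold. Exons 7 and 8 of ERCC4 had a ratio of 0 in all 3 PMA-labelled libraries, where it had no back-splice read, and 0.963 ± 0.0641 in the medium-labelled ones (SD, n = 3). Exons 5 and 6 of FNDC3A (chromosome 13, 49138747 to 49145935) had 0 against 0.952 ± 0.0826, on 0 reads against 9. Of 1273 ratios tested with limma, 0 passed, with a smallest adjusted p of 0.151 for ERCC4 and FNDC3A and 74 at an unadjusted threshold of 0.05 (32 higher, 42 lower). The other 3 lower ratios of smallest p were of SOCS7, PPA2 and a junction at CPSF1P1 and SLC5A4-AS1, each with an adjusted p of 0.326. The 5 higher ones were of RNF216, MED1, GTF2IP20, SLC4A4 and RAB6A, on 6 to 16 reads over the PMA-labelled libraries. Shifts of up to 0.6 on the arcsine scale were recovered in 0 of 40 simulated circRNAs.

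The amount and diversity of circRNA overlapped between the groups. Back-splice reads came to 12828 ± 5608 in the PMA-labelled and 10874 ± 2760 in the medium-labelled libraries (exact permutation p = 0.6, SD, n = 3 each). Scaled to mapped reads they came to 177 ± 11.1 and 208 ± 34.0 RPM (exact permutation p = 0.2). The number of circRNAs with at least 1 read was 6146 ± 2027 against 5586 ± 1103 (exact permutation p = 0.7), and after thinning to the smallest library 4055 ± 131 against 4059 ± 107 (exact permutation p = 1). With at least 2 reads it was 2332 ± 1025 against 1967 ± 494 (exact permutation p = 0.6). The median junction ratio was 61.1% ± 9.64 against 63.5% ± 5.54 (exact permutation p = 1). It was 50% in PMA-labelled library 1 and 57.1% in medium-labelled library 2, those of fewest back-splice reads, and 66.7% in each other library. A ratio of 0 was kept where a library had no back-splice read, so this measure also depends on depth. The 10 most abundant circRNAs took 5.27% ± 0.269 against 5.53% ± 0.241 of back-splice reads (exact permutation p = 0.2). Exonic circRNAs took 93.1% ± 0.456 against 93.2% ± 0.0905 (exact permutation p = 1), intronic ones 6.06% ± 0.369 against 5.93% ± 0.0772 (exact permutation p = 0.5) and intergenic ones 0.540% ± 0.124 against 0.495% ± 0.0475 (exact permutation p = 0.6). Antisense circRNAs took 0.275% ± 0.0412 against 0.409% ± 0.0185, lower in all 3 PMA-labelled libraries (exact permutation p = 0.1, the smallest possible, and 0.8 after Benjamini-Hochberg adjustment over 12 measures).

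The change of a circRNA and that of its host gene had a correlation close to 0. Over 739 circRNAs of 541 tested host genes, Spearman's rho of the 2 log2 fold changes was 0.0724 (bootstrap 95% interval -0.00173 to 0.146, permutation p = 0.0497) and Pearson's r was 0.0612. This correlation is across circRNAs, which share libraries and host genes and are not independent replicates, and the permutation p does not allow for that. The log2 fold changes of circRNAs had an SD of 0.979 and those of host genes 0.267. Tested circRNAs had a median of 15 reads, and counting error in their changes pulls rho towards 0. A low rho thus does not show that circRNAs change apart from their hosts. With at least 5 reads in 3 libraries rho was 0.154, above the bootstrap interval.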

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

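Leaving out medium-labelled libraries 2 and 3 together, at either correlation, and rescaling TPM to protein-coding genes were chosen after seeing the data, and all other settings before. The 3 genes past the threshold became 6 at a pseudocount of 0.1 (1 higher, 5 lower), 0 at a pseudocount of 5, 0 of 20877 without a TPM minimum, 10 under median-ratio scaling (2 higher, 8 lower) and 8 with TPM rescaled to protein-coding genes. Without the minimum many more genes were tested, but whether that ended the calls was not tested. FOSB then had a limma adjusted p of 0.247 at an unchanged log2 fold change. For the other settings the cause was not tested either. Rescaling to protein-coding genes kept the pseudocount of 1 on larger values, so it also acted as a smaller pseudocount. The log2 fold change of FOSB was -4.72 in that setting and -4.49 at a pseudocount of 0.1, against -3.38 as set beforehand. FOSB, IER3 and NR4A1 were all among the calls at a pseudocount of 0.1 and under both rescalings. At a pseudocount of 5 their log2 fold changes were -1.90, -0.88 and -1.20, with adjusted p of 0.0525, 0.0741 and 0.164. Leaving out 1 library gave 2 to 19 genes. FOSB and IER3 passed in all 6 of these fits and NR4A1 in 4, not without PMA-labelled library 2 or 3. The 19, without medium-labelled library 1, include collagen and other matrix genes, and there were 5 without medium-labelled library 2. With medium-labelled libraries 2 and 3 both left out 3 genes passed, of which 1, FOSB, was among the 3 of the full comparison; the log2 fold changes of IER3 and NR4A1 were then -2.15 and -2.61.

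The 5 gene lists past the threshold became 0 with an estimated correlation, 5 to 8 when 1 library was left out (8 without PMA-labelled library 2) and 3 with medium-labelled libraries 2 and 3 both left out (0 with an estimated correlation). Without the TPM minimum there were also 5, with fibroblast and epithelial markers in the place of NF-kB targets. All 5 were among the calls under quantile normalization, under median-ratio scaling and with TPM rescaled to protein-coding genes, which gave 6 each. The authors' sheet numbers subjects 1 to 3 in each group, as the titles do, and no source used here says what a number shares. The values did not settle whether libraries were paired. Correlations of same-number deviations were 0.0990, 0.0142 and 0.221, and those of different numbers ran from -0.184 to 0.0958. Medium-labelled library 2 correlated better with PMA-labelled library 1 (0.0958) than with its own number. Each other library correlated best with its own number, in part by small margins. With the replicate block 5 genes passed (FN1 among them) and 8 lists, and 0 circRNAs and 0 junction ratios.

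The count of circRNAs was 0 in every other setting run, DESeq2 and the fits without 1 library included, and 1 without a read minimum. The count of junction ratios was 0 in every setting run. The difference in back-splice reads of 1955 became -28.2 reads per 1000000 total reads, where unequal depth is taken out, and without 1 library it ran from -567 to 4974. The Spearman correlation of circRNA against host change was 0.154 with at least 5 reads in 3 libraries, and 0.0438 to 0.118 without 1 library; the cause was not tested. Among single genes named by the rule, alternatives ended a call in 10 cases and brought one in 2 (COL1A1 and COL1A2, without medium-labelled library 1); among single lists they ended a call in 15 cases and brought one in 18. No gene or list past the threshold turned its direction in any setting run. Of simulated 8-fold circRNA changes, 29 of 66 were recovered, and 8 of 8 among circRNAs with at least 50 reads in all.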

Other observations

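The 6 tests of explanations below were chosen only after the results were seen, while the counts over other splits of the libraries were set before.

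Matrix, protease-inhibitor and cytoskeleton genes typical of fibroblasts were measured mainly in medium-labelled libraries 2 and 3. FN1, which encodes fibronectin, was at 7.10, 73.5 and 44.2 TPM in medium-labelled libraries 1 to 3 and 1.27, 2.79 and 3.00 TPM in PMA-labelled libraries 1 to 3. SPARC, a collagen-binding glycoprotein, was at 2.28, 22.8 and 12.4 TPM and at 0.899, 0.949 and 0.955 TPM. Neither passed over all genes with limma (adjusted p = 0.224 and 0.236), though both passed without medium-labelled library 1 (0.00205 each) and FN1 passed with the replicate block (0.0216), and they were chosen after their values were seen. TIMP1, an inhibitor of matrix proteases, was at the floor in PMA-labelled libraries 1 and 2, at 0.834 TPM in PMA-labelled library 3 and at 1.29, 15.9 and 9.53 TPM in medium-labelled libraries 1 to 3.

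FOSB, IER3 and NR4A1 were higher in the medium-labelled libraries, as were 13 of 16 and 6 of 6 tested members of their lists by mean log2 value, although both list calls were lost with an estimated correlation (adjusted p = 0.413 and 0.276). Scaling of the libraries is argued against for the 19 genes tested in either of these overlapping lists. After median-ratio scaling their median log2 fold change was -0.836 (quartiles -1.48 to -0.269), with FOSB, IER3 and NR4A1 still past the threshold. RNA of fibroblast-like cells is argued against too for these 19 genes. Their median log2 ratio of medium-labelled library 2 over 1 was 0.0411 (quartiles -0.0993 to 0.114), against 2.63 for fibroblast markers. Those markers were listed after the data were seen, but COL1A1 belongs to a list fixed beforehand. It was at 4.36 TPM in medium-labelled library 1 and 42.8 TPM in library 2. Titles exchanged between the groups and a true fall of these genes by 24 h of treatment cannot be told apart by these values, since both give the same direction. The submitters' short names (Neg and pos) and group codes (C and T) sound opposite to the titles, but no source used here says which are right. Other causes were not tested. A further 17 activation genes were above the floor but too low to be tested. Of these, 23.5% (4 genes, exact 95% interval 6.81 to 49.9) lay higher in every medium-labelled than in every PMA-labelled library and 0 lay lower in every one. The interval takes genes as independent, though they share libraries. Exchanged titles and a true fall give the same direction, so no such share could decide between them.

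The fibroblast and epithelial list fixed beforehand passed, lower in the PMA-labelled libraries, without the TPM minimum (adjusted p = 0.00418, and 0.794 with an estimated correlation). Of 16 tested genes in a list of fibroblast markers written after the data were seen, 0 passed over all genes, while 40 of all 44 (90.9%) were higher in both medium-labelled libraries 2 and 3 than in every PMA-labelled library, and 30 of them also in medium-labelled library 1. Scaling does not remove this, with a median log2 fold change of -2.29 over the 16 after median-ratio scaling (quartiles -2.64 to -1.77). Over the 16, the median log2 ratio of medium-labelled library 2 over 1 was 2.63 (quartiles 2.38 to 2.91), with 1.68 for library 3 over 1. Levels of these genes were thus unequal within the group, but the list was written after these values were seen. It therefore gives no independent test of a response of equal size in all medium-labelled libraries. RNA of fibroblast-like cells in medium-labelled libraries 2 and 3 stays open as a hypothesis without an independent test, since the share of 90.9% restates what led to the list, and an unequal response of the cells themselves was not tested. The markers include 6 genes of the fixed lists and 6 with a mean of at least 1 TPM in the PMA-labelled libraries.

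With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. As many genes past the threshold as the real 3 came from 1 of the 10 splits, with 0 as the highest of the others, and as many lists as the real 5 from 1 of the 10, with 3 as the highest of the others. The other splits gave 2, 3, 0, 2, 2, 0, 2, 2 and 3 lists at the preset correlation. Most of them thus also called lists. All 10 splits gave at least the real 0 circRNAs, with a highest other of 1, and all 10 gave the real 0 junction ratios, with a highest other of 0. For circRNAs read in every library of 1 group and none of the other, 7 of the 10 splits gave at least the real 121, and the highest other gave 206.

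The antisense gene class took 1.00% of TPM in PMA-labelled library 1 and 0.0142% to 0.0215% in the other 5 libraries.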
